A study of Mus musculus with 2 samples.

How the data were processed

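Total RNA of dissected implantation sites was extracted with Tri reagent and a column kit, and biotinylated cRNA was made from 2 microg of it and hybridised to Affymetrix mouse arrays, per the labels' protocols. The labels assign 1 array to control and 1 array to homozygous Cbs null females. Whether animals or sites were pooled for an array is not given, and 1 array per genotype gives no replicate check.

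The deposited values are intensity on a linear scale, 1 per probe set and array. They were made with GCOS 1.4, per the submitters' processing notes. The algorithm within it, the genome build behind the probe sets and detection calls are not given in the sources used here. The 2% trimmed mean over all probe sets was 200.08 on both arrays, which is what scaling to a common target gives, so the values were used without further scaling. The median signal was 68.8 in control and 71.4 in Cbs null, and the highest signals were 10590.7 and 10838.5. The number of arrays limits the precision, and signal over background limits dim genes.

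Of 22690 probe sets, 64 controls were set aside and 22626 were used. Gene names came from the platform annotation, with symbols checked through gene identifiers in a RefSeq gene table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. A single gene symbol was given for 20380 probe sets, of which 20351 matched by identifier, several symbols for 691 and none for 1555. Probe sets with several symbols or none were left out of gene results. No coordinates are given, because no build is named for the probe sets.

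Values under a floor of 14.3, the 25th percentile of both arrays, were raised to it. That applied to 24.9% of control and 25.0% of Cbs null values. Probe sets were kept where the mean of the 2 signals was at least its median, 70.5, which left 11315 probe sets, 10406 of them with a single gene, and 7079 of 12393 genes. None of the kept probe sets had a value at the floor. Each gene was represented by its probe set with the highest mean signal. The result per gene is the log2 ratio of Cbs null over control, with no p-value. The median log2 ratio of kept genes was 0.02, and 95% of them lay between -0.48 and 0.58. That range was -0.53 to 0.66 in the dimmest tertile of signal and -0.41 to 0.46 in the brightest.

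Gene lists, 26 in number with 672 genes, covered methionine and sulfur metabolism, decidualization, conceptus tissues, immune cells, epithelium, endothelium, muscle, fat, ovary and oviduct, and general pathways. Of their genes 396 were measured, and 4 of these are in 2 lists (Gclc, Gclm, Lcn2 and Ltf). The median of each list was placed among 10000 random lists of the same size matched on deciles of mean signal, and a list was said to stand apart under percentile 2.5 or over 97.5. Lists with fewer than 5 measured members are given as values only. These percentiles describe the 2 arrays. They do not measure variation between animals.

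Genes were named by a fixed rule. It takes Cbs, the 12 largest ratios in each direction among kept genes with both values above the floor and no other kept probe set of opposite sign, and from each list up to 4 members at least 2-fold apart or, with none, the 2 brightest. It adds up to 5 genes per direction with a bound at the floor, of which there were none, and up to 6 per direction with several kept probe sets that were all at least 2-fold apart in the same direction. The rule gave 60 genes besides Cbs. Sdc4 and Cuedc1 were left out of the largest ratios because their probe sets had opposite signs. Other genes are named as examples of their list or as later picks, chosen after their values were seen. The groups, the lists, the thresholds, the naming rule and the alternatives other than those named below as added were fixed before the data were examined.

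Alternatives were quantile normalization, centring on the median, removal of a loess trend on signal with a span of 0.3, floors at the 10th and 40th percentiles, a pseudocount in place of the floor, filters at the 25th and 75th percentiles and no filter, the median over probe sets of a gene, leaving out probe sets that may match several transcripts, and random lists that were not matched or matched on 20 bins. Added after the data were seen were 5 list medians with some members left out. The scripts were tested on simulated data of 7038 genes built from these arrays for this comparison. A 2-fold limit found 3 of 65 genes changed 1.5-fold, 61 of 61 changed 3-fold, 62 of 62 changed 6-fold and 0 of 6850 unchanged genes. Of 100 lists of 15 unchanged genes 5 lay outside the percentile limits, and 100 of 100 lists shifted by 0.3 lay above the upper limit. The simulated noise was independent between probe sets and of 1 size at every signal. In the real arrays the SD of log2 ratios was 0.31 in the dimmest tertile and 0.25 in the brightest. These counts therefore check the scripts and give no rate of false calls in the real arrays. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.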

Results

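Implantation sites, the segments of pregnant uterus that hold an embryo with the maternal tissue around it, were profiled on Affymetrix mouse arrays on day 8 of pregnancy. RNA came from 4-month-old females on a mixed C57BL/6J and Ola129 background. The control group had 1 array and the group of females without functional Cbs had 1 array. Cbs encodes cystathionine beta-synthase, which joins homocysteine and serine to form cystathionine. The question was which transcripts differ in implantation sites of females that lack this enzyme. The labels used here name the uteri by genotype, and the genotype of the conceptus within a site is not given. Below, Cbs null sites are sites from Cbs null females. With 1 array per genotype there was no replicate check, so every difference below describes these 2 arrays and no test between genotypes was possible. The number of arrays limits the precision. After filtering, 7079 genes were compared, and log2 ratios are given as Cbs null over control. The correlation of log2 signal across the 11315 kept probe sets was 0.981 (Pearson, across probe sets, which are not independent replicates).

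Cbs itself gave little signal on either array. Its 2 probe sets read 30.3 and 29.9 on the control array and 23.8 and 22.3 on the Cbs null array, with log2 ratios of -0.35 and -0.42. Both lay below the signal filter, at percentiles 34.0 and 33.5 of mean signal, and the ratio of the brighter probe set was 0.00 with a floor at the 40th percentile of signal. The labels do not say which part of Cbs was deleted, so these values do not check the genotype. Enzymes of methionine and sulfur metabolism, the pathway around Cbs, did not stand apart from other genes. The median log2 ratio of 24 measured members was -0.03, at percentile 12.0 of random lists matched on signal, and none was 2-fold apart. Ahcyl1, a relative of S-adenosylhomocysteine hydrolase, had a log2 ratio of 0.05, and Sqor, which oxidises sulfide in mitochondria, had -0.35. Among members picked after their values were seen, Mtrr, which reactivates methionine synthase, had 0.83 and Cdo1, which oxidises cysteine, had 0.81. Suox was the lowest member, at -0.56, and 14 of the 24 members had a ratio below 0.

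Afp, Spink1, Inmt and Prss28 had the highest ratios in Cbs null sites, and the 12 lowest included 4 granzymes of uterine natural killer cells. In all, 44 genes (0.622%) were at least 2-fold higher and 20 (0.283%) at least 2-fold lower, while 6811 genes (96.2%) differed by less than 1.5-fold. The largest ratio was that of Afp, the fetal plasma protein made by yolk sac endoderm, which read 24.7 in control and 384.6 in Cbs null, 15.6-fold higher. Its control value was dimmer than the 2 values of Cbs on the same array, so the fold is imprecise, and the log2 ratio of 3.96 was 3.28 with a floor at the 40th percentile and 3.35 with a pseudocount. Spink1, a secreted inhibitor of trypsin, was 8.72-fold higher, from 556.3 to 4853.2. Inmt, a methyltransferase that uses S-adenosylmethionine, was 8.25-fold higher, from 51.0 to 420.9. Slc15a2, a transporter of small peptides, was 4.03-fold higher, Rpgrip1, a protein of photoreceptor cilia, 3.75-fold, and Wfdc18 3.71-fold. Cxcl17, a chemokine of mucosal tissues, was 3.15-fold higher, and Smim27 3.04-fold.

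The lowest ratio was that of Ctnnd1, the catenin p120 that stabilises cadherins, which was 3.43-fold lower, at 277.2 in control and 80.7 in Cbs null. The desmosomal cadherin Dsc2 was 2.64-fold lower. Alb, serum albumin, was 2.47-fold lower, Scin, an actin-severing protein, 2.26-fold, Dmkn 2.21-fold, and Cox6b2, a subunit of cytochrome c oxidase, 2.15-fold. The transcript 2510039O18Rik was 2.41-fold lower in its brightest probe set, but its other probe set had a log2 ratio of -0.28. Each of these lower genes except 2510039O18Rik rested on a single kept probe set, as did Afp, Spink1, Inmt, Prss28, Slc15a2, Rpgrip1, Wfdc18, Cxcl17 and Smim27 among the higher ones. The counts depended on the signal filter, with 149 genes higher and 79 lower when the filter was set at the 25th percentile, and 23 higher and 8 lower at the 75th.

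**Figure D1:**
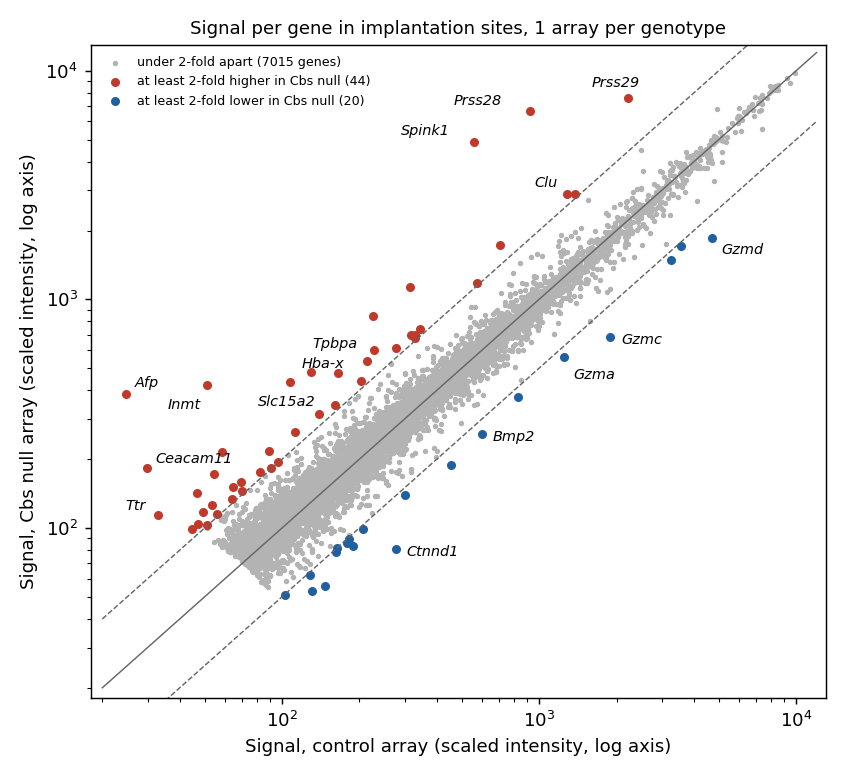
Signal of each of the 7079 kept genes on the control array (horizontal, log axis, scaled intensity) against the Cbs null array (vertical, log axis, scaled intensity), with 1 point per gene, the solid line at equal signal and dashed lines at 2-fold. The 44 genes at least 2-fold higher in Cbs null are red and the 20 at least 2-fold lower are blue, with Afp, Spink1 and Prss28 far above the line and Gzmd, Gzmc and Ctnnd1 below it.

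Uterine natural killer cell genes were lower in Cbs null sites. These cells fill the decidua in early pregnancy and carry granzymes and perforin in their granules. Of 15 measured genes of this list, 13 had a ratio below 0 and 5 were at least 2-fold lower, with a median log2 ratio of -0.85 (quartiles -1.10 and -0.45) at percentile 0 of 10000 matched random lists. Gzmc was 2.76-fold lower, from 1892.5 to 686.9, Gzmd 2.54-fold, from 4720.7 to 1857.0, Gzma 2.24-fold and Gzme 2.18-fold. Both probe sets of Gzmd were over 2-fold lower. Gzmc to Gzmg are near-identical genes, so the share of each in these signals is uncertain. The 10 other members had a median of -0.55, also at percentile 0, a split chosen after the values were seen. Among them were Prf1, perforin, at -0.96 and Il2rb, a chain of the interleukin 2 and 15 receptors, at -0.85. In contrast, Klrk1 and Tyrobp, an adaptor also found in myeloid cells, both stood at 0.05. Il15, the cytokine bound by the interleukin 15 receptor, was also counted in the list, at -0.10.

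Genes of macrophages and antigen presenting cells were higher. Their 21 measured members had a median log2 ratio of 0.30 (quartiles -0.00 and 0.52) at percentile 100, with 15 above 0 and none 2-fold apart. H2-Aa, a chain of MHC class II, had a ratio of 0.52. The 2 highest members, H2-Ab1 and Cd68, picked after their values were seen, had 0.97 and 0.83. The 6 members below 0 included Adgre1 at -0.00 and Fcer1g, the lowest, at -0.27. Lyz1, lysozyme, had 0.34, but its other probe set had -0.31. Ptprc, which all leukocytes carry, had -0.06. Of the neutrophil and acute inflammation list 4 members were measured, too few for a percentile. S100a8, a major neutrophil protein, had -0.35, while Lcn2 and Ltf, which the epithelium list also holds, had 1.04 and 0.93, and Saa3 had 0.46. Of the lymphocyte list only Ighm, the heavy chain of immunoglobulin M, was measured, at 0.94, and the ratios of its 4 probe sets ran from -0.31 to 0.94.

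Uterine epithelial genes were higher in Cbs null sites. Of 18 measured members 16 had a ratio above 0, and 5 were at least 2-fold higher. The median was 0.50 (quartiles 0.29 and 1.01), at percentile 100. Spink1 was the highest, followed by Prss28 and Prss29, the implantation serine proteinases made in uterine glands. Prss28 was 7.28-fold higher, from 918.9 to 6692.4, and Prss29 was 3.43-fold higher, from 2220.1 to 7620.0, with 2.81 to 4.01-fold over its 3 probe sets. Calb1, a calcium-binding protein of the uterine epithelium, was 2.20-fold higher from a low signal, at 47.3 and 104.2, and under 2-fold, at 0.94, with a pseudocount. Other secreted products of the list lay lower than these 3 genes, with Wfdc2 at 0.45, Ltf at 0.93 and Lcn2 at 1.04. Krt8 and Krt18, the keratin pair of simple epithelia, had 0.55 and 0.64, Epcam 0.39 and Cdh1, E-cadherin, -0.02. Outside the list, Pigr, which carries IgA across epithelia, was 2.20-fold higher, and Clu, the secreted chaperone clusterin, 2.25-fold, each in all of its kept probe sets. The fat cell list, at a median of 0.56, and Ovgp1 of the oviduct, at 1.09, were higher on the same array.

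**Figure D2:**
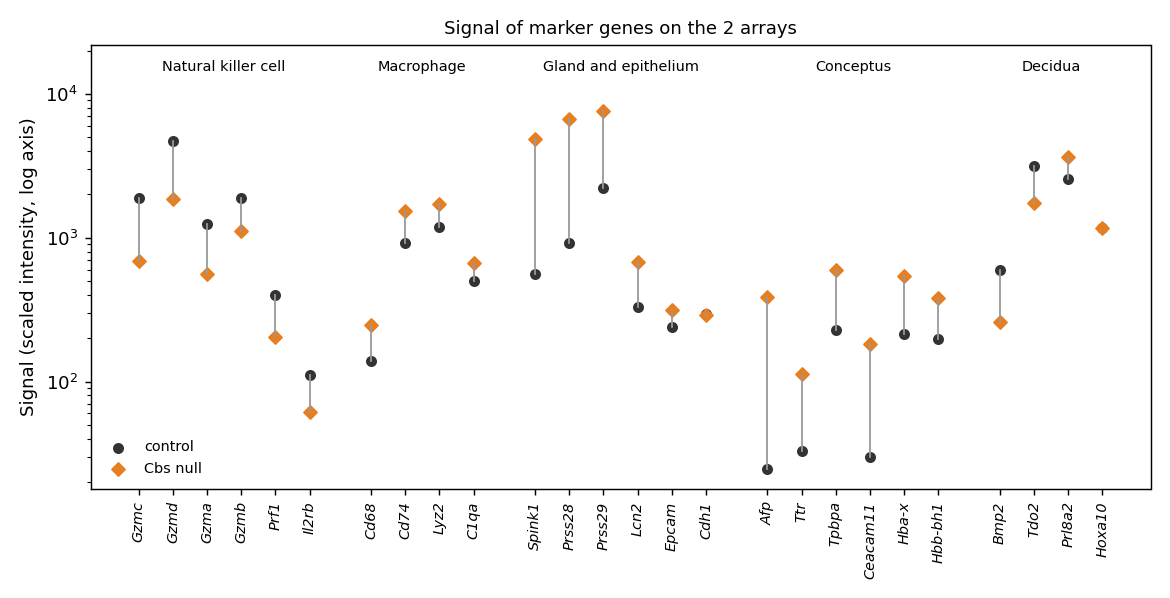
Signal of example genes of 5 tissue groups, some picked after their values were seen, on the control array (circles) and the Cbs null array (diamonds), on a log axis of scaled intensity, with 1 point per array and no error bars because each genotype had 1 array. Granzymes were lower on the Cbs null array, and Prss28 (918.9 and 6692.4) was higher.

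Some genes of the conceptus were higher in Cbs null sites, while the lists they belong to were mixed. Of 7 measured trophoblast genes, 3 were at least 2-fold higher, 4 had a ratio above 0 and 3 below. The median log2 ratio was 0.93 at percentile 100. Ceacam11, Prl2b1 and Prl4a1, the member at the median, read 29.8, 64.4 and 61.2 in control, under the filter of 70.5. They passed it through their Cbs null value, so the difference itself helped decide which members were measured, and the percentile leaves that out. Ceacam11, a member of the carcinoembryonic antigen family, had log2 ratios of 2.62 and 2.07 in its 2 probe sets, which may both match several transcripts. It read only 29.8 in control, so the size is imprecise, and the brightest probe set had 2.21 with a floor at the 40th percentile and 2.16 with a pseudocount. Tpbpa, a marker of spongiotrophoblast, was 2.62-fold higher, from 228.1 to 598.7, and Prl2b1, a placental member of the prolactin family with close relatives, was 2.34-fold higher. Eomes, which natural killer cells also express, had -0.58. The trophoblast call depended on the filter, since with dimmer genes let in, at the 25th percentile, 19 members had a median of 0.09 at percentile 68.3. Embryonic red cell genes had a median of 0.44 over 8 members, at percentile 100, which rested on the globins. Hba-x was 2.52-fold higher, from 214.0 to 539.1, Hbb-bh1 had 0.94 and Hbb-y 0.85, and the 5 other members had a median of 0.02. The 7 measured yolk sac endoderm genes, of 26 on the array, had ratios above 0, but their median of 0.11 lay at percentile 82.4. With the filter at the 25th percentile, 16 members had a median of 0.04. Afp and Ttr, the thyroxine carrier that visceral endoderm also makes, were the 2 members at least 2-fold higher, and both passed the filter through their Cbs null value. Ttr read 33.0 in control and 113.6 in Cbs null, in a single kept probe set that may match several transcripts. Its log2 ratio of 1.78 was 1.52 with a floor at the 40th percentile and 1.44 with a pseudocount. The fat cell and epithelium lists were higher on the same array, at 0.56 and 0.50. None of the 27 genes of the embryo proper on the array passed the filter, nor did any of the 5 Y-linked genes.

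Genes of decidualization, the change of uterine stroma into the tissue that surrounds the embryo, did not shift as a group. The median of 33 members was -0.02, at percentile 20.5. Bmp2, a growth factor needed for decidualization, was the only member at least 2-fold apart in its brightest probe set, 2.31-fold lower, from 597.0 to 258.0. Tdo2, which degrades tryptophan in decidual cells, had -0.84 and, in its other probe set, -1.01, and the decidual prolactin Prl8a2 had 0.52, both picked after their values were seen. Hoxa10 and Wnt4, regulators of the decidual response, had 0.02 and 0.03. Natural killer cell genes, which lie in the same tissue, had a median of -0.85 in the same samples.

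Fat cell genes were higher, with a median of 0.56 over 8 members at percentile 100 and 7 members above 0. Thrsp, a regulator of fatty acid synthesis, was 2.20-fold higher, from 278.0 to 610.7, and under 2-fold, at 0.94, with the median over its probe sets. Fabp4 and Adipoq, the fatty acid carrier and the hormone of adipocytes, had 0.81 and 0.72, whereas Plin4, a lipid droplet protein, had -0.50. Of the cholesterol and fatty acid synthesis genes only Scd1, a fatty acid desaturase, was 2-fold apart, at 2.09-fold higher in its brightest probe set and 2.30-fold in the other. That list of 18 had a median of -0.05 at percentile 8.10. Steroid hormone genes had a median of 0.34 over 7 members at percentile 99.95, with Hsd17b11 at 0.34 and Hsd11b2, which inactivates glucocorticoids, at -0.26, and with a filter at the 25th percentile the median was 0.11 at percentile 88.7. Ovgp1, the oviduct glycoprotein, was 2.12-fold higher and Inhba, a subunit of activin, had 0.36. They were the 2 measured members of the ovary and oviduct list.

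Endothelial and angiogenic genes were slightly lower. Their 23 members had a median of -0.11 at percentile 0.53, with Cd34 at -0.20 and Plvap, a protein of capillary fenestrae, at -0.36. Hypoxia and glycolysis genes had a median of -0.09 over 19 members, at percentile 2.475, close to the lower limit, and 6 alternatives moved it inside. Adm, the vasodilator adrenomedullin, went the other way and was 2.08-fold higher, from 69.9 to 145.5, and under 2-fold, at 0.92, with a pseudocount. Ribosomal protein genes had a median of 0.06 at percentile 97.7, close to the upper limit, and quantile normalization gave 0.03 at percentile 70.6. The list also lay inside the limits with loess (percentile 96.42), a filter at the 25th percentile (96.11) and no filter (95.45). The same held without probe sets that may match several transcripts (97.46) and with unmatched random lists (75.8). Rps14 had 0.05 and Rps18 -0.00.

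The remaining lists did not stand apart. Cell cycle genes had a median of -0.04 at percentile 8.39, with Rrm2, which makes deoxynucleotides, at -0.54 and Pcna at -0.09. Endoplasmic reticulum stress genes had -0.07 at percentile 4.55, with the chaperones Hspa5 at 0.03 and Calr at -0.03. Medians were 0.03 for antioxidant genes (Gpx1 at -0.13, Gpx3 at 0.06), 0.07 for interferon response genes (Ifitm3 at 0.10, Iigp1 at 0.13) and -0.04 for mitochondrial respiration genes (Cox5b at 0.07, Cox7a2 at -0.03). Smooth muscle genes had 0.02 (Acta2 at 0.02, Tpm2 at 0.03), and extracellular matrix genes had 0.02 (Col3a1 at 0.11, Sparc at -0.10). Their percentiles were 75.4, 81.1, 22.6, 72.2 and 85.8 in that order. Of the 21 lists with at least 5 measured members 10 stood apart, where 1.05 would lie outside the limits if members varied independently. Genes of a list can vary together, which that number leaves out.

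**Figure D3:**
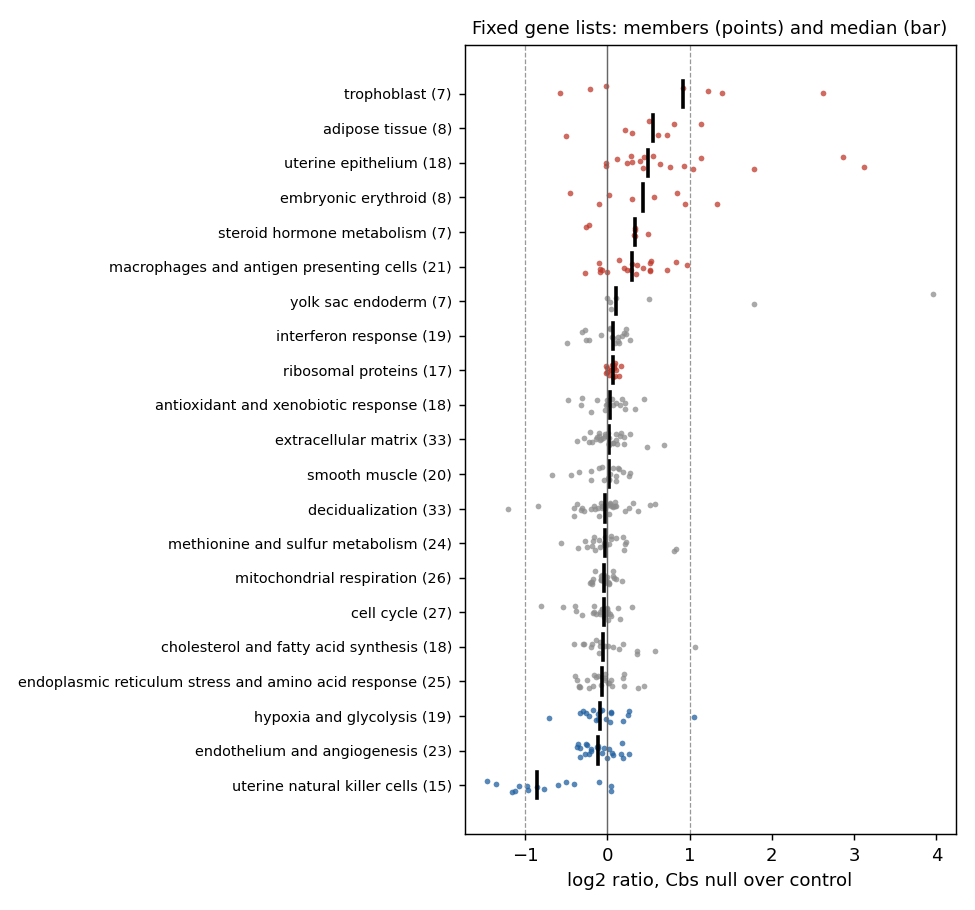
Log2 ratio (Cbs null over control, horizontal axis) of each measured member of the 21 gene lists with at least 5 of them (points, number in parentheses), with a black bar at the median, dashed lines at 2-fold, and red or blue for lists that stood apart above or below. Uterine natural killer cell genes lie lowest at -0.85, and the trophoblast, adipose and uterine epithelium lists lie highest.

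The ratio of 3' to 5' signal was 1.07 in control and 1.15 in Cbs null for Gapdh, and 1.54 and 1.61 for beta-actin. The 18 hybridization spike-in probe sets had a median log2 ratio of 0.11. All 3 probe sets of 18S ribosomal RNA were lower on the Cbs null array, with log2 ratios of -0.43, -0.66 and -0.90. The repeated measure within these arrays was the probe sets of the same gene. Among 2284 genes with several kept probe sets, the 2 brightest had ratios of the same sign in 1415 (62.0%, 95% Wilson interval 59.9 to 63.9), and their difference had an SD of 0.30. Of the 15 such genes at least 2-fold apart, 12 had the same sign in both and 7 were 2-fold apart in both.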

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

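Of the tests below, those of cross-hybridization, of the shares of leukocytes and epithelium, and of a larger share of conceptus were chosen after the result was seen.

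A signal appeared in probe sets that the gene comparisons did not use. Of 909 kept probe sets without a single gene name, 7 (0.770%) were at least 2-fold higher and 2 at least 2-fold lower on the Cbs null array. The share higher was close to the 0.622% of genes with a name, so it does not stand out.

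Natural killer cell genes were lower in Cbs null sites. The tables argue against cross-hybridization among Gzmc to Gzmg as the only source, since the 10 other members had a median of -0.55. Those members still included Gzma and Gzmb, and how far the near-identical genes share signal is not shown by this split. A signal-dependent trend is argued against by a natural killer cell median of -0.89 once it was removed. An equal fall of all leukocytes is argued against by the macrophage list, at 0.30. Whether leukocytes were fewer in total is not settled by that list, since Ptprc, which all of them carry, had -0.06. Variation between animals or dissections unrelated to genotype cannot be told apart from genotype with 1 array per genotype. Fewer or less mature natural killer cells in Cbs null decidua may be a candidate explanation, which was not tested.

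Uterine epithelium genes were higher. A signal-dependent trend is argued against by a median of 0.51 once it was removed. If a larger share of epithelium were the only source, and other cells gave no signal, all members would be higher by about 1 factor. The members ran from -0.02 to 3.13, wider than the SD of 0.30 between probe sets of a gene, which argues against that simple form. The 10 structural epithelial genes had a median of 0.35, which neither shows nor excludes a larger share of epithelium in the RNA, because the part of their signal that comes from other cells is unknown. Markers of other tissues were higher on the same array, the adipose list at 0.56 and Ovgp1 of the oviduct at 1.09. That share, variation between animals or dissections with 1 array per genotype, and an effect of the genotype on the epithelium stay open.

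Some conceptus genes were higher, although the trophoblast median was 0.09 with the filter at the 25th percentile, and the embryonic erythroid median was 0.02 without 3 globins. The lowest median of the 3 conceptus lists was 0.11, in yolk sac endoderm at percentile 82.4, which does not settle whether 1 larger share of conceptus was present, since maternal cells also express some of these genes. A difference in stage, in dissection or between animals (1 array per genotype) may also be the source and cannot be told apart from genotype.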

How the results depend on the processing

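Leaving out list members was chosen after the result was seen. Medians of the natural killer cell, macrophage, epithelium, endothelium and adipose lists stood apart under every alternative run on them, and ranged from -1.07 to -0.45, 0.27 to 0.33, 0.43 to 0.59, -0.15 to -0.09 and 0.26 to 0.67. Centring and the floors at the 10th and 40th percentiles left the percentile of each list unchanged, so they add no check on these calls. The count of higher genes was 149 with the filter at the 25th percentile or with no filter and 23 at the 75th, against 44. The count of lower genes was 79, 79 and 8 there and 13 with a pseudocount, against 20. The filters change how many dim genes enter, and all 44 and 20 genes stayed among the 149 and 79, as a looser filter must give. The pseudocount kept the same number of genes and pulls ratios of dim genes toward 0. The share of genes with probe sets of the same sign was 59.6% at the 25th, 64.9% at the 75th and 54.9% with no filter. Cbs had 0.00 with a floor at the 40th percentile, which lies above both of its values. The trophoblast median was 0.090 at the 25th percentile and 0.00 with no filter, the steroid median 0.11 and 0.00, and the embryonic erythroid median 0.022 with no filter and 0.022 without the globins. The hypoxia median was -0.067 with quantile normalization, -0.089 with loess, -0.086 with a pseudocount, -0.076 at the 75th percentile and -0.061 without probe sets that may match several transcripts, and its percentile was 2.95 with 20 bins. The ribosomal median was 0.025 with quantile normalization, 0.068 with loess, 0.065 at the 25th percentile and with no filter, and 0.078 without such probe sets, and its percentile was 75.8 with unmatched lists. Under each of these hypoxia and ribosomal alternatives the list no longer stood apart. For the changes in list medians the cause was not tested. Cell cycle genes stood apart, at -0.08, with the median over probe sets. Of 637 values of named genes under an alternative 10 moved by more than 0.30, the SD between probe sets of a gene, and 627 by less. Many of the 627 could not move that far. The filters leave the brightest probe set of a gene in place, the floor at the 10th percentile touches no kept gene, and centring shifts all ratios by 0.02. Of 35 named genes at least 2-fold apart none changed sign, but 4 came under 2-fold in at least 1 alternative (2510039O18Rik, Thrsp, Adm and Calb1). Some genes had no value under some alternatives and were not checked there. Ceacam11, Ttr, Gzme, Wfdc18 and Ovgp1 had none without probe sets that may match several transcripts. Medians near 0 (decidualization, smooth muscle, antioxidant and matrix) crossed 0 under some settings. The largest move was 2510039O18Rik, at -0.28 without its shared probe set. The trophoblast and yolk sac lists at the 75th percentile had too few members for a value. Ratios of RNA quality lie within an array, so scaling was not varied for them. The signal filter moved the counts most, and the floors at the 10th and 40th percentiles left them at 44 and 20. No paired analysis was possible because each genotype has 1 array.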

Other observations

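The genes in this part were chosen after their values were seen, and no explanation was tested for them.

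Klrg1 and Klra7, receptors of natural killer cells, had log2 ratios of -0.81 and -0.82. Fst, follistatin, which binds activins and is made in decidua, had -0.78, from 1838.3 to 1071.8, and S100a4, a calcium-binding protein of motile cells, had -0.93. Krtdap and Krt84, genes of cornified epithelia, had -0.75 and -0.71, beside Dmkn and Dsc2 of the report, and Il1r2, a decoy receptor for interleukin 1, had -1.07.

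Sfrp2, a secreted modulator of Wnt signalling, had 1.18, and Dkk3 had 1.11 in its brightest probe set and 0.46 in the other. Mmp3, a matrix protease, had 1.04 and Ctse, cathepsin E, 1.52. The retroviral gene Erv3 had 1.10. Among imprinted genes Peg3 had 0.98 in its brightest probe set and 0.25 in the other, Igf2 had 0.52, Mest 0.15 and Meg3 -0.05. Inmt was alone among the methyltransferases looked at, since Nnmt had 0.26, Gamt -0.04 and As3mt -0.18.

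Genes next to Cbs, 100 on each side in order along the chromosome of GRCm38.p6, did not stand out. Of 92 kept genes 0 were at least 2-fold apart, and their median absolute log2 ratio was 0.16 against 0.14 over all genes, at percentile 84.4 of random lists.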
